A study of Caenorhabditis elegans with 26 samples.

How the data were processed

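RNA was taken from age-synchronised whole day 1 adults of 5 strains with Trizol and a column cleanup, and libraries were made after poly(A) enrichment, per the labels' protocols. The authors deposited a table of whole-number read counts per gene and library; the submitters' processing notes name STAR 2.7.11b and the genome build ce11. The counting tool, the strand setting, the annotation release and any filter are not given in the sources used here, so that reads of overlapping and antisense genes cannot be told apart. The table has 42533 gene symbols, of which 40782 matched the Ensembl annotation of WBcel235, the same assembly as ce11; symbols without a match held 3.60% of the counts. Positions come from that annotation. A symbol gfp is part of the table.

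Counts were used as deposited. Library totals lay between 9659877 and 15528669. Genes were kept with edgeR's filterByExpr by strain, which left 13315, and scaled by TMM; CPM values are edgeR's, on that scale. edgeR 4.0.16 (R 4.3.3) was run with robust quasi-likelihood fits on all 26 libraries with terms for strain and for batch, and p was adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05. The common biological coefficient of variation was 8.01%. 4 comparisons were made against AEF231 and 2 against AEF373. Of 37 gene lists, 36 had at least 3 tested members and were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, with an estimated correlation and with fry; the other list, of 12 mitochondrially encoded genes, had none under the names used. flp-17 was also tested by a two-sided exact permutation test of mean log2(CPM + 0.5).

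Design, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took flp-17 and hsp-4, the promoter genes of the arrays, the 6 largest changes each way among genes past the threshold with a mean of at least 2 CPM and no overlap between the strains' libraries (4 between array strains), up to 4 members of each list that passed camera and up to 2 of each other list. F11C3.1 meets it; aex-5, gfp and the embryo and larval lists of the closing section were chosen after their values or related values were seen. Alternatives were other size factors, DESeq2 1.42.0, other filters, no batch term, batch 1 alone, a block for the replicate number, only the strains compared, a fit without robust weights, stricter thresholds, controls split between comparisons, other pseudocounts for flp-17, other list tests, and each library left out. Fits within each batch and without germ line and embryo lists, the embryo list without hch-1 and gcy-31 in AEF373 were added after the data were seen. The fit was tested on simulated counts with 100 genes changed by 0.5 and 100 by 1 log2 unit per comparison against AEF231, drawn from the real means: 54, 65, 62 and 60% of the smaller and 91, 89, 89 and 85% of the larger changes were called in AEF276, AEF378, AEF373 and AEF149, with 9, 9, 6 and 5 false calls among 12743, 12755, 12747 and 12737 genes. The changed genes were drawn from those with a mean of at least 1 CPM in AEF231, so that recovery was not tested for lower genes. Libraries were checked for repeated columns: over 55 pairs of replicates the chi-square per gene lay between 3.32 and 14.2, above sampling noise in each pair.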

Results

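Poly(A) RNA of whole day 1 adult Caenorhabditis elegans was sequenced from 5 strains that differ in flp-17, the gene of the FMRFamide-like neuropeptide FLP-17 of the BAG sensory neurons, in 26 libraries. AEF231 carries an hsp-4 promoter::GFP reporter of the unfolded protein response of the endoplasmic reticulum (ER) and was the control (n = 6). AEF276 adds the loss-of-function allele n4894 of flp-17 (n = 5). The other strains hold extrachromosomal arrays. AEF276, AEF378 and AEF373 share the background of AEF231. In AEF378 flp-17 fused to GFP is driven by the promoter of gcy-31, a guanylate cyclase gene of the same neurons, with a red coelomocyte marker (n = 5). In AEF373 flp-17 is driven by its own promoter with its own 3' untranslated region, with an unc-122 promoter::mCherry marker (n = 5). In AEF149 flp-17 fused to GFP is driven by the flp-17 promoter with a myo-3 promoter::mCherry marker, in the background of the parent of AEF231 that had not been outcrossed (n = 5). Array strains were sorted for their marker 24 h before collection while AEF231 and AEF276 were only washed and replated, so that array and handling cannot be told apart by these samples alone. Batch 2 held 6 libraries, from AEF231, AEF378 and AEF373, and batch 1 the other 20. Total counts per library lay between 9659877 and 15528669, and 13315 genes were tested. The labels call the libraries replicates without saying whether they came from separate cultures, so p-values measure the spread between these libraries.

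flp-17 (WBGene00001460, chromosome IV, 17190204 to 17191891, minus strand, WBcel235) was read at a mean of 3.8 ± 1.49 CPM (counts scaled to library size, SD, n = 6) in AEF231 and at 0.310 ± 0.307 (n = 5) in AEF276. It was read at 7.59 ± 1.01 CPM in AEF378, 301 ± 29.3 in AEF373 and 388 ± 23.4 in AEF149 (SD, n = 5 each). The log2 fold changes against AEF231 were -3.63 ± 0.44 (SE) in AEF276, 0.99 ± 0.21 in AEF378, 6.29 ± 0.14 in AEF373 and 6.66 ± 0.15 in AEF149. The adjusted p was 4.73e-06, 0.00256, 1.83e-19 and 1.68e-19 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All libraries of each strain lay on one side of all AEF231 libraries. In a two-sided exact permutation test over 462 splits the adjusted p was 0.00433 for AEF378 and 0.00289 for each of the other strains, whose raw p of 0.00216 is the smallest the splits can give. Between array strains, flp-17 was 0.37 ± 0.11 log2 higher in AEF149 than in AEF373 (edgeR adjusted p = 0.0116). Reads of a transgene cannot be told from those of the chromosomal gene.

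The table also counts a sequence named gfp, which it does not describe; the hsp-4 reporter and 2 of the arrays hold GFP. It stood at 67.8 ± 9.18 CPM in AEF231 (SD, n = 6) and at 75.2 ± 4.51 in AEF276 (SD, n = 5). It was 2.44-fold higher in AEF378 and 13.4-fold higher in AEF149, both of which hold GFP arrays, and 1.07-fold in AEF276 (edgeR adjusted p = 1.08e-12, 1.21e-23 and 0.435). It was also 1.92-fold higher in AEF373, whose array is given with mCherry and no GFP (edgeR adjusted p = 2.96e-10). Its mean was 163 CPM in AEF378 and 129 CPM in AEF373. flp-17, which the AEF378 array fuses to GFP, was read in AEF378 at a mean of 7.59 CPM. The array of AEF378 is thus not shown to be the source of its gfp rise, and the source was not tested. hsp-4 itself (WBGene00002008, chromosome II, 7350112 to 7352645), which encodes the ER chaperone BiP, was read at 467 ± 36.4 CPM in AEF231 and 567 ± 54.2 in AEF276, a log2 fold change of 0.28 ± 0.06 (edgeR adjusted p = 0.00121). The change was 0.17 ± 0.06 in AEF149 (adjusted p = 0.0492), 0.11 ± 0.06 in AEF378 (adjusted p = 0.224) and -0.03 ± 0.06 in AEF373 (adjusted p = 0.753). The call in AEF149 ended without AEF149 replicates 1, 2, 3 and 5 and without AEF231 replicates 1 and 2, at adjusted p between 0.0648 and 0.115. In AEF373 the sign turned without AEF231 replicates 4 or 5 or AEF373 replicates 3 or 5, at values up to 0.0121.

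**Figure D1:**
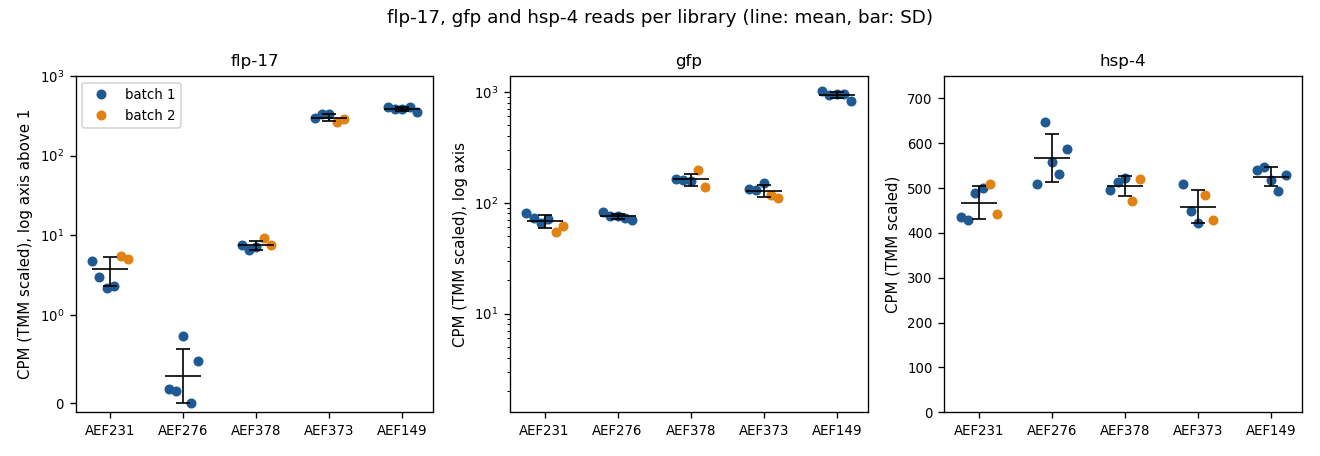
CPM of flp-17, gfp and hsp-4 in each library (points; colour gives the batch) of the 5 strains, with the mean and SD of each strain; the flp-17 axis is logarithmic above 1, the gfp axis is logarithmic and the hsp-4 axis is linear. flp-17 rises from AEF276 (mean 0.31 CPM) over AEF231 and AEF378 to AEF373 and AEF149 (mean 388 CPM).

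The loss-of-function strain AEF276 was compared with AEF231 to show what changes without FLP-17. Sperm genes had the lowest median of the 36 lists, at a log2 fold change of -3.04, and fell in 39 of 50 (43 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation). msp-38 and msp-49, which encode major sperm proteins, changed by -3.94 ± 0.39 and -3.85 ± 0.36 (SE, n = 5 against 6), and nspd-2, a nematode-specific sperm peptide gene, by -3.60 ± 0.35. Oogenic germ line and eggshell genes rose in 34 of 49 (42 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation), by small amounts, such as the chondroitin proteoglycan gene cpg-4 at 0.30 ± 0.05 and the P-granule gene pgl-3 at 0.33 ± 0.06. Collagens fell in 37 of 98 (43 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation), among them col-81 at -1.71 ± 0.22 and col-129 at -1.65 ± 0.22.

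ER unfolded protein response genes and chaperones were higher in AEF276 in 9 of 34 (17 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation) and none were lower. cup-2, a Derlin gene of ER quality control, was at 0.30 ± 0.05 and uggt-1, a glycoprotein folding sensor, at 0.20 ± 0.05. Proteasome subunits rose in 14 of 33 (22 adjusted over the list alone, adjusted p = 0.126 with an estimated correlation), with rpn-6.1 at 0.20 ± 0.05. Body wall muscle genes fell in 13 of 23 (13 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation), with the myosin light chain mlc-1 at -0.36 ± 0.05 and the troponin I gene tni-1 at -0.50 ± 0.10. Intestinal genes fell in 9 of 25 (10 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation), with the intestinal actin act-5 at -0.39 ± 0.07. Among single genes pqn-73 was at 2.73 ± 0.65 and hil-7, a linker histone gene, at 1.79 ± 0.40, while gst-4, a glutathione S-transferase used as a reporter of SKN-1, was at -0.70 ± 0.13. Over all genes tested, 1496 were higher and 1209 lower in AEF276 (adjusted p below 0.05), of which 29 and 483 by at least 2-fold. In camera with a preset correlation of 0.01, 14 of 36 lists passed, sperm at adjusted p = 9.77e-28, oogenic genes at 2.19e-18, the ER list at 1.43e-05 and collagens at 6.61e-13, and none of them held with an estimated correlation (adjusted p between 0.117 and 0.471).

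The count of genes higher in AEF276 was sensitive to single libraries. It was 608, 628, 869, 985, 948 and 788 without AEF231 replicates 1 to 6 in turn, and 606 and 771 without AEF276 replicates 2 and 3. All AEF276 libraries were in batch 1, and with batch 1 libraries alone 645 genes were higher and 963 lower. msp genes are near-identical copies, so that how their reads were shared between copies is uncertain.

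AEF378, with flp-17 under the gcy-31 promoter and the smallest rise in flp-17, was compared with AEF231. The strains also differ in the marker and in sorting, so that the changes cannot be credited to flp-17 alone. Genes of the intracellular pathogen response, a programme induced by microsporidia and viruses, rose in 7 of 10 (7 adjusted over the list alone, adjusted p = 0.0125 with an estimated correlation). eol-1 was at 2.85 ± 0.53 and the Skp1-related genes skr-5 and skr-4 at 1.35 ± 0.20 and 0.61 ± 0.11 (log2 fold change ± SE, n = 5 against 6). Moulting and larval cuticle genes rose in 8 of 21 (9 adjusted over the list alone, adjusted p = 0.0527 with an estimated correlation), with the zona pellucida domain genes noah-1 at 1.58 ± 0.12 and noah-2 at 1.70 ± 0.16. PMK-1 associated immunity genes rose in 11 of 27 (13 adjusted over the list alone, adjusted p = 0.126 with an estimated correlation), including the lysozyme genes lys-3 at 1.98 ± 0.37 and lys-2 at 0.76 ± 0.10. Cytosolic ribosomal protein genes fell in 24 of 77 (43 adjusted over the list alone, adjusted p = 0.144 with an estimated correlation) and proteasome genes in 12 of 33 (23 adjusted over the list alone, adjusted p = 0.126 with an estimated correlation), such as rps-20 at -0.25 ± 0.06 and rpn-7 at -0.18 ± 0.05. Oogenic germ line genes fell in 15 of 49 (20 adjusted over the list alone, adjusted p = 0.211 with an estimated correlation), with gld-1, a regulator of translation in the germ line, at -0.28 ± 0.05.

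Among genes with a mean of at least 2 CPM and no overlap between the libraries of the strains, the largest rise in AEF378 was in F11C3.1 (WBGene00008695, chromosome I, 14867924 to 14871365) at 5.06 ± 0.11, and the largest fall in ztf-28, a zinc finger gene, at -2.41 ± 0.17. gcy-31 was at 1.29 ± 0.45 (edgeR adjusted p = 0.0459), from 0.477 ± 0.239 CPM in AEF231 (SD, n = 6), and at 1.15 ± 0.45 in AEF373 (adjusted p = 0.0419), whose array is not given with its promoter. The difference between these strains was 0.14 ± 0.42 (adjusted p = 0.884; below 0 without AEF373 replicate 1 or AEF378 replicate 1, at -0.03 and -0.07). The call in AEF378 ended without any 1 of AEF231 replicates 1 to 5 or AEF378 replicates 1, 3, 4 and 5, at adjusted p between 0.0527 and 0.141. The call in AEF373 ended without AEF231 replicates 2, 3 or 5 or AEF373 replicates 2, 3 or 5, at 0.0630 to 0.128. Pan-neuronal genes rose in 4 of 20 (6 adjusted over the list alone, adjusted p = 0.126 with an estimated correlation), with the syntaxin gene unc-64 at 0.55 ± 0.10. In all, 1022 genes were higher and 788 lower, of which 245 and 13 by at least 2-fold. By camera 16 of 36 lists passed, of which the intracellular pathogen response held with an estimated correlation and the others did not (adjusted p between 0.0527 and 0.398). Within batch 1, 642 genes were higher and 329 lower. Within batch 2, with 2 libraries a strain, 276 were higher and 88 lower. 0 genes differed between batches in edgeR's test of the difference (665 at an unadjusted p below 0.05). With batch 1 libraries alone the counts were 597 and 427.

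AEF373, with untagged flp-17 under its own promoter and a large rise in flp-17, was compared with AEF231. The strains also differ in the marker and in sorting, so that the changes cannot be credited to flp-17 alone. Moulting and larval cuticle genes rose in 13 of 21 (14 adjusted over the list alone, adjusted p = 0.00842 with an estimated correlation). noah-1 was at 2.71 ± 0.12, mlt-11, a protease inhibitor gene needed for moulting, at 3.64 ± 0.23, and mlt-8 at 2.54 ± 0.22 (SE, n = 5 against 6). Among epidermal and cuticle genes 10 of 31 rose and 7 fell (11 and 8 adjusted over the list alone), with the furrow collagen dpy-7 at 4.02 ± 0.32 and dpy-17 at 3.95 ± 0.28 while dpy-4 was at -2.84 ± 0.73. That list had an adjusted p of 0.294 with an estimated correlation, and without AEF231 replicate 3 it did not pass camera with the preset correlation (adjusted p = 0.0636). Single genes with large rises were the collagen col-165 at 6.74 ± 0.78, pqn-73 at 6.44 ± 0.48 and the cuticlin cut-3 at 5.67 ± 0.60. PMK-1 associated immunity genes rose in 16 of 27 (16 adjusted over the list alone, adjusted p = 0.119 with an estimated correlation), with T24B8.5 at 1.38 ± 0.16, and DAF-16 associated genes in 10 of 18 (10 adjusted over the list alone, adjusted p = 0.0844 with an estimated correlation), with lea-1 at 1.51 ± 0.11. Intracellular pathogen response genes rose in 7 of 10 (7 adjusted over the list alone, adjusted p = 0.0844 with an estimated correlation), with eol-1 at 3.17 ± 0.51.

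Cytosolic ribosomal protein genes fell in AEF373 in 50 of 77 (54 adjusted over the list alone, adjusted p = 0.153 with an estimated correlation), proteasome genes in 27 of 33 (29 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation) and nuclear oxidative phosphorylation genes in 23 of 33 (24 adjusted over the list alone, adjusted p = 0.0952 with an estimated correlation), with medians of -0.22, -0.20 and -0.19. Vitellogenin genes, which encode yolk proteins, fell in 4 of 6 (4 adjusted over the list alone, adjusted p = 0.279 with an estimated correlation), with vit-3 at -0.81 ± 0.08 and vit-1 at -0.86 ± 0.10. Body wall muscle genes rose in 14 of 23 (15 adjusted over the list alone, adjusted p = 0.153 with an estimated correlation), with myo-3, a myosin heavy chain, at 0.72 ± 0.08, and pan-neuronal genes in 12 of 20 (12 adjusted over the list alone, adjusted p = 0.119 with an estimated correlation), with unc-13 at 0.52 ± 0.09. Both lists changed less in batch 2: the muscle medians were 0.30 and 0.11 within batches 1 and 2 (adjusted p = 0.000397 for the difference, camera with the preset correlation only). The neuronal medians were 0.56 and 0.20 (adjusted p = 0.00487 by the same test), and within batch 2 that list did not pass camera (adjusted p = 0.0929). F11C3.1 was at 5.16 ± 0.11 and unc-122, whose promoter the marker carries, at 1.13 ± 0.20. In all, 2385 genes were higher and 2244 lower, of which 737 and 49 by at least 2-fold. Of 17 lists that passed camera, the moulting list held with an estimated correlation, and the others did not (adjusted p between 0.0844 and 0.514). Within batch 1, 2275 genes were higher and 2040 lower, and within batch 2 571 and 254, and 25 genes differed between batches (edgeR, Benjamini-Hochberg). The moulting list had medians of 1.22 and 0.88 within batches 1 and 2, and the sperm list -0.94 and -0.08.

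**Figure D2:**
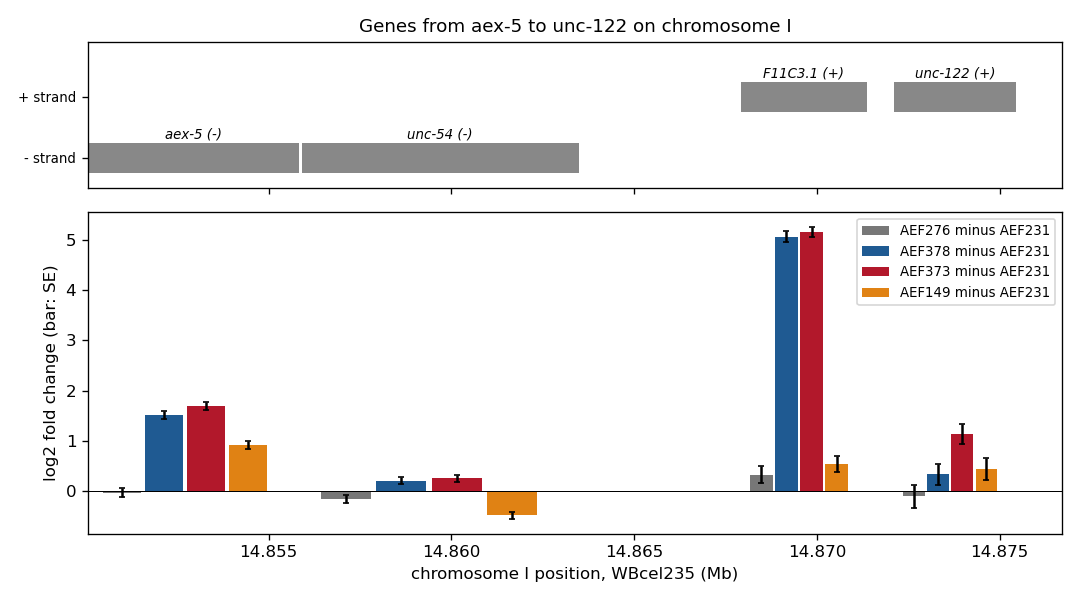
Map of 4 genes (aex-5, unc-54, F11C3.1 and unc-122, other genes not drawn) on chromosome I with their strands (x axis, position in Mb), and their log2 fold changes against AEF231 in AEF276, AEF378, AEF373 and AEF149 (bars, with SE as lines). F11C3.1 was at 5.06 ± 0.11 in AEF378 and 5.16 ± 0.11 in AEF373.

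**Figure D3:**
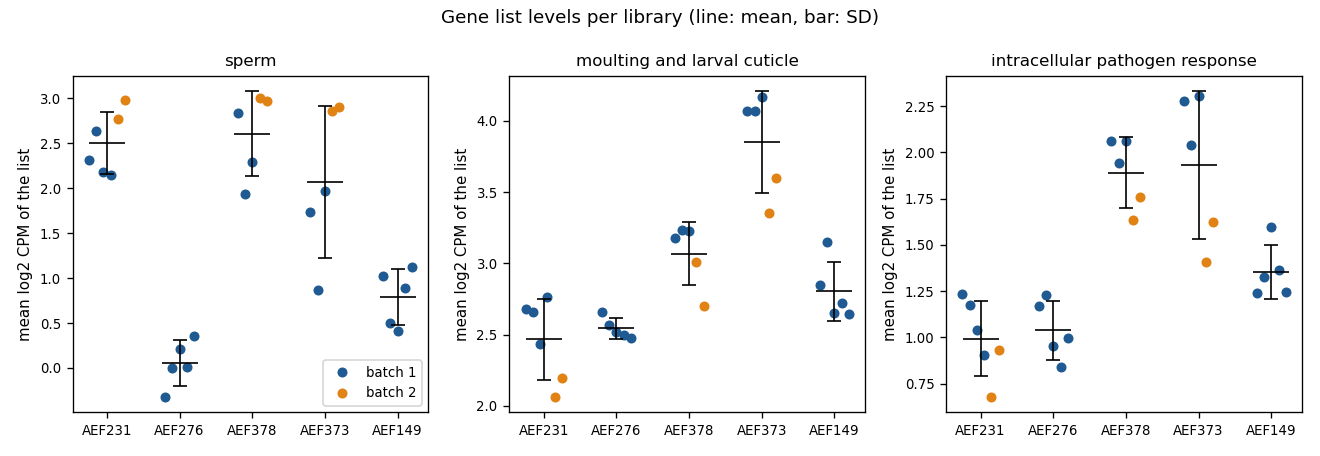
Mean log2 CPM of the sperm, moulting and intracellular pathogen response lists in each library (points; colour gives the batch, not adjusted for) of the 5 strains, with the mean and SD of each strain. Sperm genes lie lowest in AEF276 (mean 0.05) and AEF149 (mean 0.79), and moulting genes highest in AEF373 (mean 3.85).

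AEF149, with the most flp-17 reads, was compared with AEF231, from which it also differs in background because it was not outcrossed. Sperm genes fell in 36 of 50 (39 adjusted over the list alone, adjusted p = 0.0922 with an estimated correlation), with a median log2 fold change of -1.77, msp-49 at -2.63 ± 0.31 and the sperm phosphatase gene gsp-3 at -2.31 ± 0.31 (SE, n = 5 against 6). Fat metabolism genes fell in 18 of 34 (19 adjusted over the list alone, adjusted p = 0.0371 with an estimated correlation), among them ech-6, an enoyl-CoA hydratase gene, at -0.39 ± 0.05 and acdh-1, an acyl-CoA dehydrogenase gene, at -0.34 ± 0.05. Collagens went both ways, with 13 of 98 higher and 35 lower (14 and 41 adjusted over the list alone, adjusted p = 0.334 with an estimated correlation), with col-167 at 3.08 ± 0.26 and col-129 at -2.51 ± 0.23. Pan-neuronal genes rose in 8 of 20 (13 adjusted over the list alone, adjusted p = 0.0463 with an estimated correlation), with rab-3 of synaptic vesicles at 1.05 ± 0.15 and unc-31 of dense-core vesicle release at 0.86 ± 0.17. FMRFamide-like peptide genes other than flp-17 rose in 7 of 29 (8 adjusted over the list alone, adjusted p = 0.0920 with an estimated correlation), with flp-6 at 0.49 ± 0.10 and flp-9 at 0.48 ± 0.13.

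Body wall muscle genes fell in AEF149 in 13 of 23 (15 adjusted over the list alone, adjusted p = 0.0847 with an estimated correlation), with the troponin T gene tnt-2 at -0.77 ± 0.06, while myo-3, whose promoter the marker carries, was at 0.20 ± 0.08 (edgeR adjusted p = 0.102). Pharyngeal genes rose in 9 of 16 (10 adjusted over the list alone, adjusted p = 0.0847 with an estimated correlation), with the pharyngeal myosin myo-2 at 0.76 ± 0.10. Nuclear oxidative phosphorylation genes fell in 17 of 33 (21 adjusted over the list alone, adjusted p = 0.0493 with an estimated correlation), with gas-1 of complex I at -0.46 ± 0.06. The small heat shock genes hsp-16.41 and hsp-16.2 were at 4.41 ± 0.58 and 3.26 ± 0.51, in a list that did not pass camera (adjusted p = 0.508, median -0.06 and mean 0.54), and PMK-1 associated genes rose in 8 of 27 (8 adjusted over the list alone, adjusted p = 0.200 with an estimated correlation), with clec-60 at 4.52 ± 0.71. In all, 867 genes were higher and 1467 lower, of which 289 and 406 by at least 2-fold. Of 13 lists that passed camera, fat metabolism, pan-neuronal and oxidative phosphorylation genes held with an estimated correlation, and the others did not (adjusted p between 0.0847 and 0.416). All AEF149 libraries were in batch 1, and with batch 1 libraries alone 989 genes were higher and 1098 lower.

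Array strains were compared with one another, AEF378 and AEF149 each against AEF373. flp-17 was -5.30 ± 0.14 log2 in AEF378 against AEF373, and moulting genes were lower in 13 of 21 (13 adjusted over the list alone, adjusted p = 0.00366 with an estimated correlation), with a median of -0.63. cut-3 was at -5.33 ± 0.64 and col-165 at -5.37 ± 0.74, while col-71 was at 1.63 ± 0.35 (SE, n = 5 against 5). In AEF149 against AEF373 moulting genes were lower in 15 of 21 (16 adjusted over the list alone, adjusted p = 0.00983 with an estimated correlation) and body wall muscle genes in 21 of 23 (21 adjusted over the list alone, adjusted p = 0.0226 with an estimated correlation), with medians of -0.89 and -0.48. Fat metabolism genes were lower in 23 of 34 (23 adjusted over the list alone, adjusted p = 0.0319 with an estimated correlation). hch-1, a hatching protease gene, was at -5.01 ± 0.39, F11C3.1 at -4.62 ± 0.11 and B0511.11 at 3.27 ± 0.14. Sperm genes were lower in 35 of 50 (39 adjusted over the list alone, adjusted p = 0.453 with an estimated correlation). By edgeR, 490 genes were higher and 788 lower in AEF378 than in AEF373, and 1764 and 2535 in AEF149 than in AEF373. Within batches 1 and 2, 469 and 66 genes were higher in AEF378 than in AEF373 and 751 and about 1.2e+02 lower, and without AEF373 replicate 1 the count of higher genes was 326.

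Loss of function and the arrays were set side by side over the 13315 genes. AEF276 and AEF149, with the fewest and the most flp-17 reads, shared 858 genes changed the same way against AEF231 and 41 changed in opposite ways, where lists of these lengths would share 231 and 244 if independent. Of the shared genes 698 were lower in both, msp-49 and col-129 among them. Both comparisons use the same controls, so that their lists are not independent. With the controls split between them, and the parts then exchanged, 445 and 455 genes went the same way and 18 and 26 opposite ways. AEF276 and AEF373 shared 316 genes the same way and 524 in opposite ways (independent lists, 472 and 469), and 337 of the latter were higher in AEF276 and lower in AEF373. The opposite count was 277, 291 and 314 without AEF231 replicates 1, 2 and 6 and 340 and 336 without AEF276 replicates 2 and 3, and the same-way count 195 without AEF231 replicate 2. AEF276 and AEF378 shared 148 the same way and 229 in opposite ways (independent lists, 186 and 181). Without AEF231 replicates 1, 2 and 3 in turn the opposite count was 142, 139 and 149, and the same-way count was 95 without AEF231 replicate 2 and 97 without AEF276 replicate 2. AEF378 and AEF373 shared 1452 the same way and 19 in opposite ways (independent lists, 316 and 313), with noah-1, noah-2 and F11C3.1 higher in both. AEF373 and AEF149, with the highest flp-17, shared 920 the same way and 181 in opposite ways (independent lists, 403 and 409). AEF149 shared more genes with AEF373 than with AEF276, both the same way and in opposite ways. AEF373 also had more genes called against AEF231 (4629) than AEF276 (2705), so that these counts alone do not say which is closer to AEF149. The correlation and covariance of fold changes, given below, were higher for AEF276 and AEF149 than for AEF373 and AEF149. AEF378 and AEF149 shared 453 the same way and about 1.1e+02 in opposite ways (independent lists, 153 and 164). Simulated strains without any change against the same controls shared 0 called genes, which sets no chance level for these counts. Across genes, which are not independent replicates, the correlation of fold changes was 0.61 for AEF276 and AEF149 (simulated without effects 0.50; 0.53 and 0.48 with the controls split), 0.20 for AEF276 and AEF373 (0.42; 0.17 and 0.11) and 0.71 for AEF378 and AEF373 (0.45; 0.58 and 0.55). The covariance was 0.193, 0.0719 and 0.163, against simulated values of 0.0210, 0.0171 and 0.0179. For AEF373 and AEF149 the correlation was 0.48, against 0.43 simulated and 0.37 and 0.41 with the controls split. For AEF378 and AEF149 the correlation was 0.36, against 0.42 simulated and 0.23 and 0.25 with the controls split. The covariance of these pairs was 0.156 and 0.0733, against simulated values of 0.0171 and 0.0172. Real changes widen the spread of fold changes, so the correlations simulated without effects set no chance level for the observed correlations.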

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

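The tests of explanations in this part, and the splits of AEF276 against AEF231, were chosen after the results they bear on had been seen; the splits of the other 5 comparisons were planned before they were run. In splits of the libraries of both strains compared, the real grouping was the 1 of 100 with the most genes past the threshold in every comparison. A random split of these libraries thus seldom gives as many genes. The splits cannot tell strain from a culture or handling that the libraries of a strain may share. In AEF276 minus AEF231 the real split gave 2705 genes and the highest other 2054. In AEF378 minus AEF231 the real split gave 1810 genes and the highest other 497. In AEF373 minus AEF231 the real split gave 4629 genes and the highest other 2506. In AEF149 minus AEF231 the real split gave 2334 genes and the highest other 328. In AEF378 minus AEF373 the real split gave 1278 genes and the highest other 248. In AEF149 minus AEF373 the real split gave 4299 genes and the highest other 1565. The highest other split of AEF276 and AEF231 exchanged 5 libraries, close to the mirror of the real one.

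Sperm genes were much lower in AEF276 (median log2 fold change -3.04). A batch effect is argued against: batch 1 libraries alone gave -3.19. Sorting cannot account for it by design, since neither AEF276 nor AEF231 was sorted. The sorted strains AEF378 and AEF149 had medians of 0.0599 and -1.77, which add no test of sorting in AEF276. A difference in adult age or stage may contribute: vitellogenin genes, which rise in early adulthood, had a median of -0.00188, which decides nothing, and the number of sperm per animal was not measured. The genotype stays open beside it.

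Moulting genes were higher in AEF373, where a median of at least 0.88 within each batch argues against batch, and AEF378, sorted and of the same background, at -0.63 against AEF373, argues against sorting as the whole cause. Sorting stays open for the part shared with AEF378 (8 of 21 higher), since AEF149, sorted but of another background, had a median of -0.000177. More or older embryos inside the animals, which a sort 24 h earlier would not remove, are a candidate explanation: mid and late embryo genes, listed after hch-1 among them had been seen, had a median without hch-1 of 0.71 in AEF373 (10 of 20 higher and 0 lower, p = 3.93e-05 in limma's camera with an estimated correlation) and 0.50 in AEF378 (7 higher and 0 lower, p = 0.00135). Early embryo genes, a list fixed before the data were examined, do not show this (3 of 19 higher, 7 lower, median -0.23, adjusted p = 0.160), and of the mid and late list 14 were read at 1 CPM or more in AEF231, 1 stands in another list, and egg-6, the most abundant, was at -0.08 ± 0.05 (SE, 495 CPM in AEF231). In AEF149 the mid and late list without hch-1 had a median of -0.08 (1 higher and 0 lower), and in AEF276 -0.33 (2 higher and 2 lower). In camera with an estimated correlation its p was 0.964 and 0.116. Larvae among the animals cannot be told apart from embryos inside them, since the larval and L4 cuticle list had a median of -0.58 in AEF373 with 4 of 14 higher and 5 lower. That list partly restates the pattern: 13 of its genes stand in a fixed list and 3 in the moulting list, mlt-10 and mlt-11 among the 4 higher. The 5 lower were bli-2, bli-6, dpy-4, dpy-5 and dpy-13.

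F11C3.1 was 33.4-fold higher in AEF378 and 35.7-fold higher in AEF373. It ends at 14871365 on chromosome I, upstream of unc-122 at 14872112, on the same strand, and the AEF373 marker carries the unc-122 promoter, so that reads from array DNA are a candidate source. AEF149, with a myo-3 marker, was -4.62 log2 from AEF373, which the array explanation needs and which argues against sorting, as AEF149 was sorted too. A response to flp-17 level is argued against, since flp-17 was 0.37 log2 higher in AEF149 than in AEF373. Whether the reads come from the array was not tested, since the table holds no read positions, and the labels do not name the promoter of the AEF378 marker.

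Total counts stood apart in AEF276 replicate 2, at 15528669 against 11845306 for the nearest library of the strain. The mean log2 CPM of the ER list was 7.68 in AEF378 replicate 2, the lowest of its strain, and that of the proteasome list 8.01 in AEF149 replicate 5, the highest; 3 of 75 groups stood out in this way, and chance gives about 1 in 20. In AEF373 against AEF231 the sperm list fell less in batch 2, with medians of -0.94 and -0.08 within batches 1 and 2. The median difference, batch 2 minus batch 1, was 0.90 log2 (limma's camera with the preset correlation, adjusted p = 3.24e-13 for the difference). The same difference was, for pan-neuronal, body wall muscle and fat metabolism genes, -0.24, -0.16 and -0.13 in AEF373. For collagens, body wall muscle and pharynx genes it was -0.23, -0.13 and -0.42 in AEF378 (adjusted p of these lists between 0.000180 and 0.00590). All p-values for differences between batches use the preset correlation, with 2 libraries a strain in batch 2. No value with an estimated correlation is given for them, and most lists that passed with the preset correlation elsewhere did not hold with an estimated one. The count for gfp, which belongs to no gene of the worm, was 2.44, 1.92 and 13.4 times that of AEF231 in AEF378, AEF373 and AEF149.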

How the results depend on the processing

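Within-batch fits, the fit without germ line and embryo lists, the embryo list without hch-1 and gcy-31 in AEF373 were chosen after the data were seen. Counts are of genes unless lists are named, and counts written with e are rounded. Over single genes and list medians, 9749 values under the alternatives kept direction and side of the threshold, 526 fell short of it and 6 changed sign. flp-17 kept both under every alternative run in the comparisons with AEF231. The changes of sign were hsp-4 in AEF373 against AEF231, never past the threshold, at 0.0056, 0.0043, 0.012 and 0.009 without AEF231 replicates 4 and 5 and AEF373 replicates 3 and 5, and gcy-31 in AEF378 against AEF373, never past the threshold, at -0.03 and -0.07 without AEF373 replicate 1 and AEF378 replicate 1. Over counts, 696 stayed within 1.5 times and 90 did not. With 1 library left out, 167 to 249 genes were higher in all 3 array strains and 114 to 181 lower. Adjusted p below 0.01 gave 108 higher in all 3 array strains, 56 lower in all 3 array strains, 12 opposite in AEF276 and AEF149, 147 opposite in AEF276 and AEF373, 52 opposite in AEF276 and AEF378, 442 same way in AEF276 and AEF149, 115 same way in AEF276 and AEF373, 51 same way in AEF276 and AEF378. Adjusted p below 0.05 and 2-fold gave 53 higher in all 3 array strains, 2 lower in all 3 array strains, 10 opposite in AEF276 and AEF149, 11 opposite in AEF276 and AEF373, 13 opposite in AEF276 and AEF378, 305 same way in AEF276 and AEF149, 35 same way in AEF276 and AEF373, 29 same way in AEF276 and AEF378. Batch 1 only gave 645 higher AEF276 against AEF231, 597 higher AEF378 against AEF231, 427 lower AEF378 against AEF231, 73 lower in all 3 array strains, 25 opposite in AEF276 and AEF149, 235 opposite in AEF276 and AEF373, 70 opposite in AEF276 and AEF378, 87 same way in AEF276 and AEF378. Camera with estimated correlation gave 3 lists in AEF149 against AEF231, 3 lists in AEF149 against AEF373, 0 lists in AEF276 against AEF231, 1 list in AEF373 against AEF231, 1 list in AEF378 against AEF231, 1 list in AEF378 against AEF373. Controls split, first parts gave 18 opposite in AEF276 and AEF149, 200 opposite in AEF276 and AEF373, 48 opposite in AEF276 and AEF378, 445 same way in AEF276 and AEF149, 128 same way in AEF276 and AEF373, 49 same way in AEF276 and AEF378. Controls split, parts exchanged gave 26 opposite in AEF276 and AEF149, 275 opposite in AEF276 and AEF373, 1.0e+02 opposite in AEF276 and AEF378, 455 same way in AEF276 and AEF149, 130 same way in AEF276 and AEF373, 60 same way in AEF276 and AEF378. Fry directional gave 22 lists in AEF149 against AEF373, 29 lists in AEF373 against AEF231. Fry mixed gave 31 lists in AEF149 against AEF231, 32 lists in AEF149 against AEF373, 27 lists in AEF276 against AEF231, 35 lists in AEF373 against AEF231, 29 lists in AEF378 against AEF231, 27 lists in AEF378 against AEF373. No low-count filter gave 15 lists in AEF378 against AEF373, 915 higher AEF276 against AEF231, 66 opposite in AEF276 and AEF149. Only the 2 strains compared gave 461 higher AEF276 against AEF231, 23 opposite in AEF276 and AEF149, 197 opposite in AEF276 and AEF373, 109 opposite in AEF276 and AEF378. Replicate block with batch gave 150 opposite in AEF276 and AEF378. Within batch 1 gave 642 higher AEF378 against AEF231, 329 lower AEF378 against AEF231. Within batch 2 gave 571 higher AEF373 against AEF231, 276 higher AEF378 against AEF231, 66 higher AEF378 against AEF373, 254 lower AEF373 against AEF231, 88 lower AEF378 against AEF231, 1.2e+02 lower AEF378 against AEF373. Without germ line and embryo lists gave 832 higher AEF276 against AEF231. With 1 library left out the ranges were -0.069 to 0.37 gcy-31 log2 fold AEF378 against AEF373, 606 to 1712 higher AEF276 against AEF231, 326 to 453 higher AEF378 against AEF373, 114 to 181 lower in all 3 array strains, 277 to 586 opposite in AEF276 and AEF373, 139 to 258 opposite in AEF276 and AEF378, 195 to 336 same way in AEF276 and AEF373, 95 to 154 same way in AEF276 and AEF378, -0.058 to 0.012 hsp-4 log2 fold AEF373 against AEF231. Lower thresholds of p, a fold minimum, split controls and single strains or batches use stricter rules or fewer libraries, and otherwise the cause was not tested. A block for the replicate number moved the calls from 2705 to 2316 in AEF276 against AEF231, 1810 to 1386 in AEF378 against AEF231, 4629 to 4201 in AEF373 against AEF231, 2334 to 2225 in AEF149 against AEF231, 1278 to 1215 in AEF378 against AEF373, 4299 to 3533 in AEF149 against AEF373. Same-numbered libraries of different strains had correlations of deviations over 0.1 in 15 of 54 pairs. For the block and for these pairs AEF231 replicate 6 was counted under number 5. Their median was 0.0554, against -0.0175 for pairs with other numbers. 5 of 26 libraries correlated best with their own number. The deviations were not adjusted for batch, and pairs of different strains both in batch 2 had a median of 0.210, against -0.0468 for pairs across batches. Whether same-numbered libraries share more than a number or a batch cannot be told from these values. Depth limits low genes: flp-17 had 17 reads in all AEF276 libraries. With 1 library left out, its log2 fold change in AEF276 against AEF231 lay between -4.25 and -3.35.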

Other observations

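Both tests in this part were chosen after the data were seen. Genes changed at least 2-fold were unevenly spread over chromosomes. In AEF378, 19 of 67 tested genes between 1500001 and 2000000 on chromosome II were higher (adjusted p = 7.18e-16, hypergeometric test). Of the same 67 genes, 7 were higher (adjusted p = 0.0862) and 12 lower (adjusted p = 4.81e-05) in AEF149. In AEF276 22 of 76 between 5000001 and 5500000 on chromosome IV were lower (adjusted p = 2.22e-12). In AEF149 19 of the same 76 genes were lower (adjusted p = 1.08e-10). The sperm list also fell in both AEF276 and AEF149, and how many of these genes are sperm genes was not counted. Genes are not independent in such a test.

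aex-5 (chromosome I, 14850052 to 14855827), which lies beside the 3' end of the myosin gene unc-54 at 14855901, was higher in all 3 array strains, at 1.52 ± 0.08 in AEF378, 1.69 ± 0.08 in AEF373 and 0.92 ± 0.09 in AEF149 (log2 fold change ± SE, edgeR), and at -0.03 ± 0.09 in AEF276.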
